A study of Rattus norvegicus with 18 samples.

How the data were processed

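Gene expression was measured in 18 samples of rat neural tissue, each hybridised to its own Affymetrix RA230 array. Per the labels, 9 arrays came from the oculomotor nucleus and 9 from the spinal cord, with 3 arrays at each of the ages 6, 18 and 30 months. Per the submitters' processing notes, each sample combined RNA from 4 animals. The same notes speak of 4 replicates per group, while the labels give 3, and the labels were followed. Whether the oculomotor and cord pools of an age share animals is not given in the sources used here.

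The authors scanned the arrays and summarised the probes with Affymetrix Microarray Suite 5.0, and the deposited table holds 1 intensity per probe set and array on a linear scale, without detection calls. Its 15923 probe sets include 57 manufacturer's controls. Scaling was read from the values, since it was not given in the notes: the 2% trimmed mean lay between 500.083 and 500.101 on every array. No centring was found, because the median intensity differed between arrays, from 252 to 275.

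Values were first brought to a common 2% trimmed mean, which changed them by factors between 0.999981 and 1.00002. Signals under the pooled 20th percentile, 66.4, were raised to that floor, and log2 was taken. After removal of the controls, probe sets were kept if their mean log2 signal exceeded the pooled 40th percentile, 7.459, which left 9482. Probe sets were named with the rat gene tables of the reference: 12789 named 1 gene, 312 named several and were given no gene name, and 2822 were absent from the platform annotation. Of those with 1 gene, 12754 were matched by Entrez identifier and 35 kept the symbol of the annotation, for 10412 genes in all.

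A linear model with a mean for each of the 6 groups was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. It had 12 residual degrees of freedom, and 18.8 with the prior. The comparisons were 18 with 6 months and 30 with 6 months in each tissue, any difference between the ages in each tissue (limma's F statistic over both age contrasts), the difference between the tissues in the change from 6 to 30 months, and the tissues at 6 months. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the probe sets kept, and a probe set was called at an adjusted p under 0.05. Overlap between the calls of the tissues was tested with Fisher's exact test, 2-sided. Fold changes are ratios of the group means of log2 signals, while group levels are means of the scaled signals with their SD.

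The 32 gene lists, written from textbook knowledge, held 893 members, of which 717 were matched to a probe set. They covered the immune system (microglia markers, complement, antigen presentation, interferon response), glia (astrocyte markers, myelin and oligodendrocyte markers, oligodendrocyte precursor and proliferation) and neurons (motor neuron and cholinergic, general neuronal and synaptic, GABA and glycine, glutamate receptors, calcium buffering and pumps, neurotrophic factors and receptors, midbrain and monoamine neurons). Others covered metabolism and upkeep of the cell (oxidative phosphorylation, glycolysis, chaperones and heat shock, antioxidant and metal binding, proteasome and ubiquitin, lysosome and lipid handling, cholesterol synthesis, ribosomal proteins, cell cycle arrest and DNA damage). The rest covered tissues that a dissection can include (extracellular matrix and meninges, vascular cells, blood and choroid plexus, Schwann cell and nerve root, skeletal muscle) and regulated programmes (Hox genes, immediate early genes, circadian clock, glucocorticoid responsive). Each gene was represented by its probe set with the highest mean. Lists were tested with limma's camera at a preset correlation of 0.01, with p-values adjusted over the 31 lists that kept enough members, since only 2 Hox genes passed the filter. Beside it stand camera with an estimated correlation and fry, a self-contained rotation test of whether the members move, on balance, in the same direction. Differences between the medians of lists were tested by permuting genes between the lists, which takes genes as independent and does not measure the spread between arrays.

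Genes are named by a fixed rule. Among probe sets that name 1 gene, passed the test and did not overlap between the groups, the 10 with the largest rise and the 10 with the largest fall are named, with 1 probe set per gene. Where fewer than 5 pass, the 10 with the smallest p are named as not past the test, and each list described adds up to 4 members with the smallest p. For 3 arrays against 3, chance gives non-overlap in 10% of probe sets. Chat, Gfap, Th and Mbp are given in all 6 groups whatever their values. The lists, this rule, the tests and most alternatives were chosen before the data were examined.

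Alternatives were quantile normalization, median centring, values as deposited, no floor, a pseudocount in place of the floor, no filter, a stricter filter at the 60th percentile, no trend, a separate fit of each tissue, array weights, replicate number as a block, a 1.70-fold criterion, the mean of all probe sets of a gene for the lists, and leaving out each array in turn. Added after seeing the data were a block for 4 arrays that stand apart, their omission, the skeletal muscle list mean as a covariate, the omission of 3 cord arrays rich in muscle transcripts, direct contrasts of 30 with 18 months, and the omission of each array in turn for the called lists. Simulated data held 200 changed probe sets of known size. In the comparison of 30 with 6 months in the oculomotor nucleus, 47.8% of log2 changes of 0.5 and 95.5% of those of 1 were recovered, with 9 false calls of 171. In the spinal cord the shares were 40.3% and 88.1%, with 21 false calls of 173, a share above the threshold of 0.05. The data gave fewer calls in these comparisons, 20 and 21, which makes the cutoff on p stricter. Recovery in the data may thus be lower than in the simulation. Array precision is limited by the 3 arrays per group. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.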

Results

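The study measured how the transcripts of the rat oculomotor nucleus and spinal cord differ with age. The oculomotor nucleus is a midbrain group of motor neurons that move the eye, and the spinal cord holds the motor neurons of the limbs and trunk. Each tissue had 3 arrays at 6 months, 3 at 18 months and 3 at 30 months, 18 in all, and the RNA on every array was pooled from 4 animals. P-values therefore measure the spread between pooled samples, not between animals. Median intensity per array lay between 252 and 275, and between 18.0% and 21.0% of the probe sets of an array lay at or under the floor of 66.4.

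Markers of motor neurons, astrocytes, dopamine neurons and myelin were followed in every group (mean ± SD, n = 3). Chat, the enzyme that makes acetylcholine, had signals of 155 ± 43.6, 114 ± 22.4 and 143 ± 32.7 in the oculomotor nucleus at 6, 18 and 30 months, and of 367 ± 61.3, 363 ± 66.0 and 375 ± 31.2 in the cord. Gfap, the astrocyte intermediate filament, had 5182 ± 238, 5882 ± 464 and 6828 ± 869 in the oculomotor nucleus and 11920 ± 1920, 11120 ± 1110 and 10720 ± 1700 in the cord. Th, tyrosine hydroxylase, had 2563 ± 290, 2488 ± 234 and 2292 ± 485 in the oculomotor nucleus, against 114.5 ± 23.3, 92.2 ± 24.6 and 87.0 ± 37.7 in the cord. Mbp, myelin basic protein, had 13360 ± 1440, 12870 ± 945 and 14350 ± 3160 in the oculomotor nucleus and 16850 ± 4710, 13520 ± 2990 and 12400 ± 2580 in the cord. None of these 4 genes passed the test in a comparison of ages.

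Arrays of the same group differed in transcripts of neighbouring tissues. Acta1, the actin of skeletal muscle, had signals of 2008, 3631 and 253 on the 3 cord arrays at 6 months, 276, 1529 and 503.5 at 18 months, and 296, 344 and 321 at 30 months. Ckm, muscle creatine kinase, followed with 680, 1227 and 111 at 6 months. Ttr, transthyretin, which the choroid plexus makes in quantity, had 3720, 164 and 124.5 on the oculomotor arrays at 6 months, 1658, 194 and 601 at 18 months, and 516.5, 129.5 and 137 at 30 months. Apart from these transcripts, 4 arrays deviated from their groups together: oculomotor 30 months replicate 3, cord 6 months replicate 1, cord 18 months replicate 3 and cord 30 months replicate 3. The first principal component of the group-centred values held 27.1% of their variance, and these 4 arrays scored between -16.6 and -12.1 on it, while no other array scored under -1.70. The highest score, 14.2, was that of oculomotor 30 months replicate 2. The 3' to 5' ratio of hexokinase, a sign of RNA quality, moved with age in the oculomotor nucleus, from 1.57 to 1.64 at 6 months to between 1.75 and 1.89 at 18 months and between 1.76 and 1.91 at 30 months. The ratios of the other control transcripts overlapped between these ages. GAPDH had 0.991 to 1.018 at 6 months, 1.009 to 1.021 at 18 months and 1.00 to 1.094 at 30 months. Beta-actin had 1.253 to 1.358, 1.219 to 1.488 and 1.315 to 1.544.

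**Figure D1:**
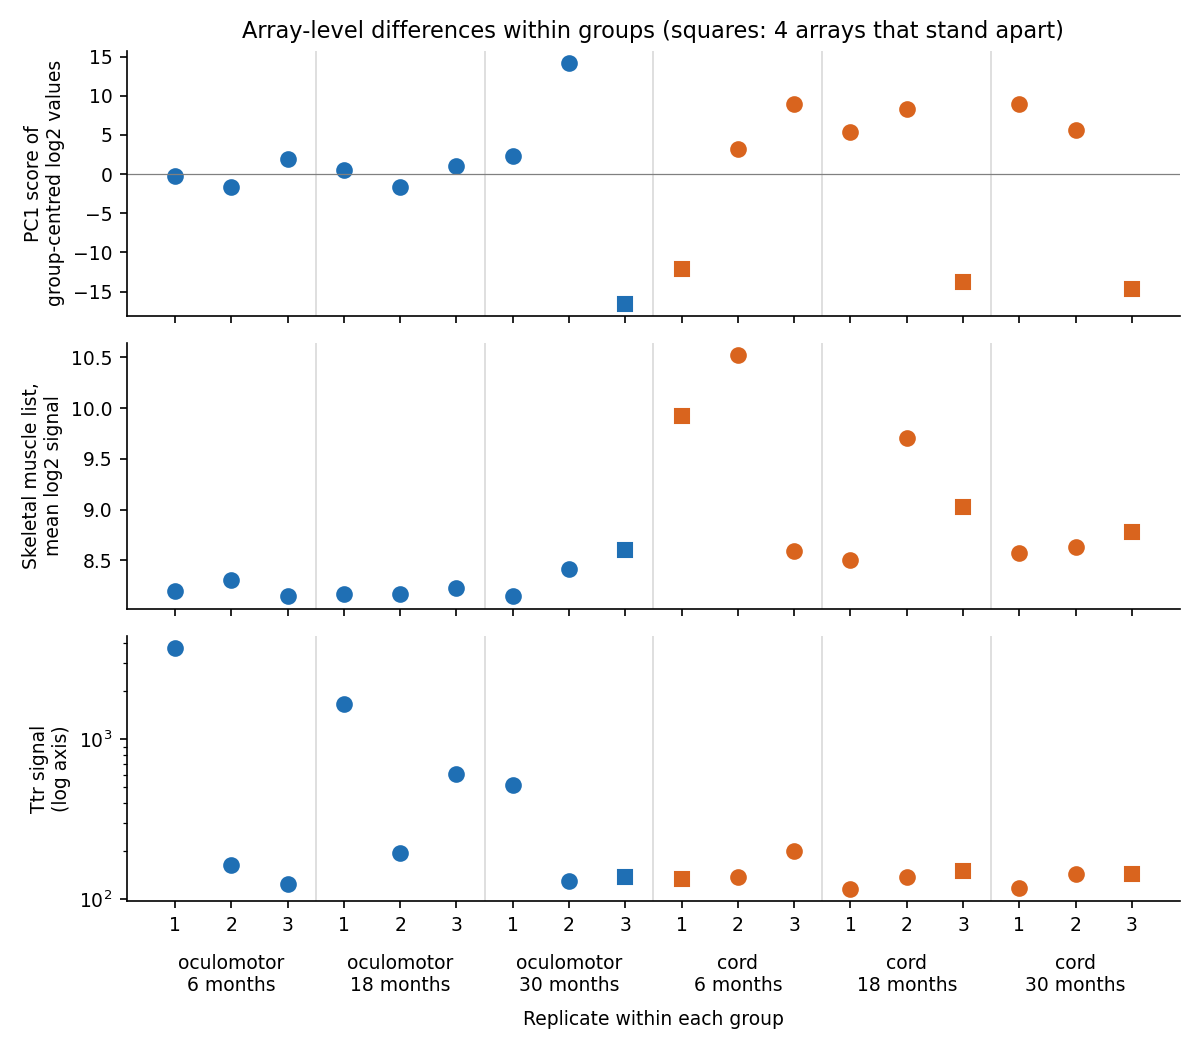
For each array, by group and replicate, the score on the first principal component of the group-centred log2 values, the mean log2 signal of the skeletal muscle list, and the Ttr signal (intensity, log axis). Squares mark the 4 arrays that score -12.1 or lower, and the muscle list has its highest means, 9.92 and 10.5, in cord 6 months replicates 1 and 2.

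The comparison of 18 with 6 months in the oculomotor nucleus asked which transcripts differ by the intermediate age. C3, the central protein of the complement cascade, had a signal of 856 ± 28.6 at 18 months and 546 ± 55.6 at 6 months (n = 3 each), 1.57-fold, and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.452). Golm1, a Golgi membrane protein, had 326 ± 2.75 against 209 ± 15.5 (1.56-fold, adjusted p = 0.452). The remaining 8 of the 10 genes with the smallest p each had an adjusted p of 0.811: R3hdm2 (log2 change 0.75), Parp9 (0.66), Mpeg1 (0.62), Cdc42se1 (0.51), Fnbp1 (0.47), Sox10 (0.44), Vat1 (0.38) and Tm9sf3 (-0.54). No probe set of the 9482 passed limma's test, and 321 had an unadjusted p under 0.05, 181 of them higher at 18 months.

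Immune lists lay above the other genes at 18 months in the oculomotor nucleus, beside the higher hexokinase ratios of these arrays. Of 18 microglia markers 14 had a positive change (median log2 0.22), with Cd53 at 0.49, Ctss at 0.48, Fcer1g at 0.40 and P2ry12 at 0.34. No marker passed over all probe sets and 2 passed adjusted over the list alone, with a camera adjusted p of 3.39e-06 (adjusted p = 0.244 with an estimated correlation). Among the antigen presentation genes 13 of 15 were positive (median 0.15), including RT1-Ba at 0.70, Cd74 at 0.57, RT1-Da at 0.53 and Ctss at 0.48. For this list 0 passed over all probe sets or adjusted over the list alone, with a camera adjusted p of 9.67e-06 (adjusted p = 0.244 with an estimated correlation). In all, camera called 10 lists, of which 0 held with an estimated correlation and 0 were called by fry.

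At 30 months against 6 months, the oculomotor nucleus had higher levels of 3 major histocompatibility complex class II genes, which present peptides to T cells, and of their invariant chain, beside the higher hexokinase ratios of these arrays. RT1-Da rose 3.47-fold, from 297 ± 16.9 to 1059 ± 321 (n = 3 each, adjusted p = 0.00019). Cd74, the class II invariant chain, rose 3.19-fold, from 453 ± 100 to 1454 ± 397 (adjusted p = 0.00127). C3 rose 2.13-fold, from 546 ± 55.6 to 1158 ± 52.4 (adjusted p = 0.000574). In the other direction, Igf2, a growth factor that meninges and choroid plexus express, fell 2.19-fold, from 1167 ± 181 to 530 ± 66.8 (adjusted p = 0.00904), beside the Ttr signals given for these arrays. Slc13a4, a sulfate transporter of the same tissues, fell 2.07-fold, from 337 ± 29.2 to 164 ± 21.3 (adjusted p = 0.00398).

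Other rises at 30 months in the oculomotor nucleus were RT1-Ba (log2 change 1.39), RT1-Db1 (1.33), Plek (1.16), the inhibitory Fc receptor Fcgr2b (1.10), the macrophage pore protein Mpeg1 (0.91), Parp9 (0.84) and Golm1 (0.83), with adjusted p between 0.0061 and 0.0448. Col1a1, a chain of type I collagen, fell by at least 1.33 (adjusted p = 0.0159), from 198 ± 47.3 to 76.2 ± 20.9, with 1 array at the floor, while its other probe set differed by -0.29. Microglia markers were the list with the smallest p: 3 of 18 rose (Fcgr2b, Fcer1g at 0.57 and Cd53 at 0.75), 10 did adjusted over the list alone, and P2ry12 at 0.61 did not pass (adjusted p = 0.126). The list's camera adjusted p was 7.43e-15 (adjusted p = 0.12 with an estimated correlation), with a median of 0.43. Of 15 antigen presentation genes 4 rose, RT1-Da, RT1-Ba, RT1-Db1 and Cd74, while the class II genes RT1-Bb at 1.08, RT1-DMb at 0.24 and RT1-DMa at 0.07 did not pass. Adjusted over the list alone 7 rose (median 0.25, mean 0.62, camera adjusted p = 1.37e-12, adjusted p = 0.12 with an estimated correlation). Complement had 1 of 8 members risen, C3, and 2 adjusted over the list alone, with C1qa at 0.72, Serping1 at 0.47 and C1qb at 0.38 not past the test (camera adjusted p = 2.84e-05, adjusted p = 0.236 with an estimated correlation).

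As lower lists at 30 months in the oculomotor nucleus, camera called the extracellular matrix and oxidative phosphorylation. Of 22 extracellular matrix and meninges genes 2 fell, Igf2 and Col1a1, and 5 did adjusted over the list alone, while Col1a2 at -0.98 (adjusted p = 0.0688) and Col3a1 at -0.62 (adjusted p = 0.163) did not pass. The list's median was -0.24 (camera adjusted p = 6.04e-06, adjusted p = 0.236 with an estimated correlation). None of 55 oxidative phosphorylation genes passed over all probe sets or adjusted over the list alone, and 5 were positive. Examples are the respiratory chain subunits Ndufs3 at -0.27, Uqcrfs1 at -0.24 and Ndufs7 at -0.23, and the ATP synthase subunit Atp5f1a at -0.28, with a list median of -0.12 (camera adjusted p = 1.23e-07, adjusted p = 0.416 with an estimated correlation). This call rested on 30-month replicate 2: without it the list mean went from -0.12 to -0.03 and the call was lost (adjusted p = 0.468). Of 7 lists that camera called, 0 held with an estimated correlation, and fry called 3, microglia markers, antigen presentation and interferon response, each with an adjusted p of 0.0278.

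Across all 9482 probe sets, limma called 20 at 30 months against 6 months in the oculomotor nucleus, 17 higher and 3 lower, for 15 and 3 named genes. The count was 10, 4 and 8 without 6-month replicates 1, 2 and 3, and 69, 8 and 7 without 30-month replicates 1, 2 and 3. It was 12 with the skeletal muscle list as a covariate, 8 with a pseudocount in place of the floor and 8 with no filter.

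**Figure D2:**
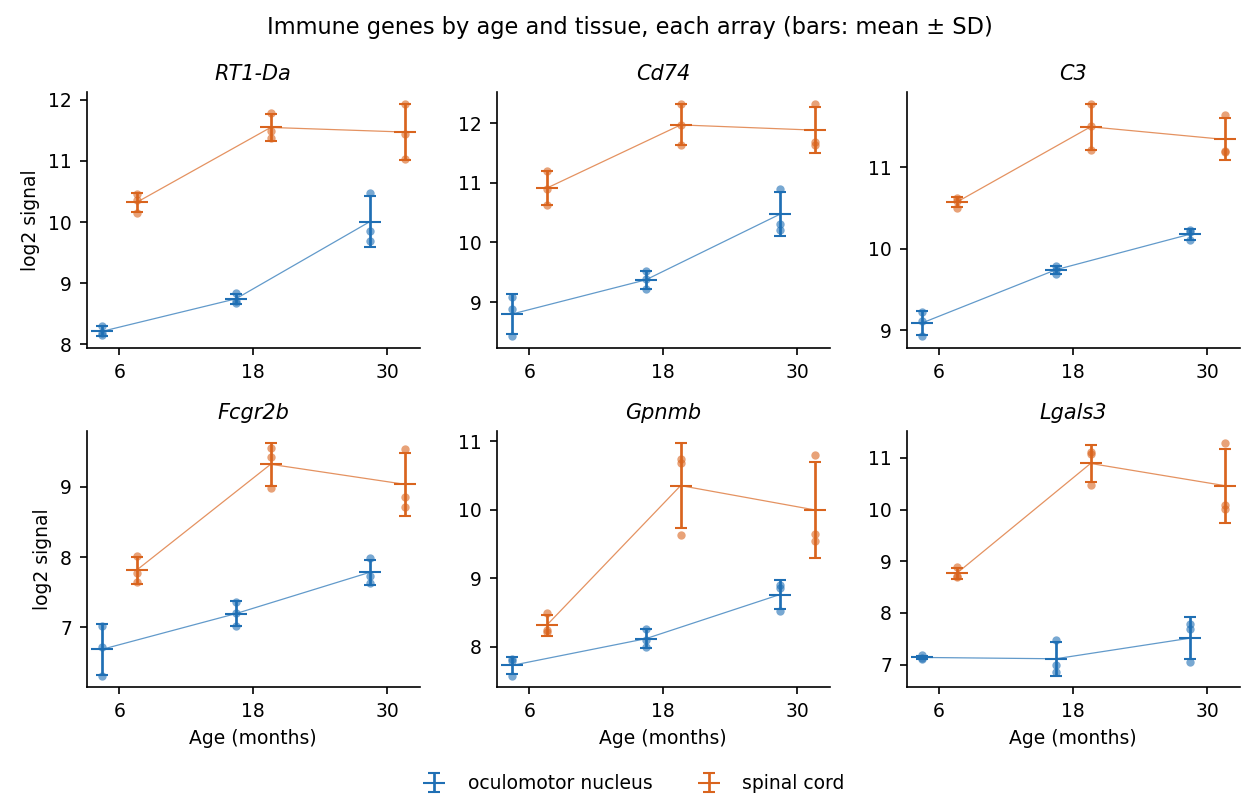
Log2 signal of 6 immune genes against age in months on each array (points), with the mean and SD of 3 arrays per group (bars) in both tissues. RT1-Da, Cd74 and C3 lie above their 6-month levels at 30 months in the oculomotor nucleus, by 1.80, 1.67 and 1.09, and Lgals3 and Gpnmb lie above theirs at 18 months in the cord, by 2.13 and 2.04.

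In the spinal cord at 18 months against 6 months, genes of activated microglia and macrophages rose and genes of cholesterol synthesis fell. Lgals3, a galectin of phagocytic cells, rose 4.37-fold, from 436 ± 34.6 to 1937 ± 443 (n = 3 each, adjusted p = 0.00225). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, rose 4.11-fold, from 319 ± 34.8 to 1384 ± 511 (adjusted p = 0.0026). The class II gene RT1-Bb rose 3.78-fold, from 362 ± 116 to 1357 ± 398 (adjusted p = 0.0026). Lss, lanosterol synthase, fell 1.61-fold, from 1143 ± 59.9 to 711 ± 70.5 (adjusted p = 0.00548), and Cyp51, lanosterol demethylase, fell 1.57-fold, from 1113 ± 144 to 706 ± 22.9 (adjusted p = 0.00468).

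Further rises in the cord at 18 months were RT1-Db1 (log2 change 1.69), Fcgr2b (1.51), Plek (1.34), RT1-Da (1.23), Timm17b (1.17), Anp32a (1.12) and Cd74 (1.06), with adjusted p between 0.0026 and 0.036. Timm17b started from 82.6 ± 62.8, with 1 array at the floor, so its rise is a lower bound. Among microglia markers 7 of 18 rose, 15 did adjusted over the list alone and all 18 were positive, with Fcer1g at 0.69 (median 0.66, camera adjusted p = 4.74e-24, and 0.0164 with an estimated correlation). Complement had 2 of 8 members risen, C3 at 0.93 and C1qa at 0.78, and 6 adjusted over the list alone, while C1qb and C1s, both at 0.83, did not pass (camera adjusted p = 3.66e-10, and 0.0449 with an estimated correlation). Of 15 antigen presentation genes 5 rose and 8 did adjusted over the list alone, led by RT1-Bb, RT1-Db1, RT1-Da and Cd74 (camera adjusted p = 1.22e-12, adjusted p = 0.0504 with an estimated correlation). The lysosome and lipid handling list of 23 had 1 rise, progranulin (Grn, 0.84), and 1 fall, the fatty acid desaturase Scd (-0.69), while Ctsz at 0.82 and Npc2 at 0.39 did not pass. Adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.000318, adjusted p = 0.27 with an estimated correlation).

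The cholesterol synthesis list held 5 falls and 1 rise among 18 members in the cord at 18 months, and 13 falls and 1 rise adjusted over the list alone. Besides Lss, Ebp fell by 1.02, Acat2 fell by 0.68, Msmo1 fell by 0.67 and Sqle, squalene epoxidase, fell by 0.62, with adjusted p between 0.0188 and 0.0462. The rise was Srebf1 (0.69, adjusted p = 0.00648), a transcription factor of lipid synthesis. The list's median was -0.47 (camera adjusted p = 7.31e-16, and 0.000264 with an estimated correlation). Its Cyp51 probe set is another than the one named above and differed by -0.59. Outside the list, Aacs fell by 0.62, the kinase Limk1 fell by 0.67 and the collagen chain Col6a1 fell by 0.63. Beside these changes, the skeletal muscle transcripts were unevenly spread over the cord arrays at 6 and 18 months, as the Acta1 signals show.

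In total limma called 69 probe sets at 18 months against 6 months in the cord, 51 higher and 18 lower, for 38 and 16 named genes. Of 11 lists that camera called, 4 held with an estimated correlation, microglia markers, complement, interferon response and cholesterol synthesis, and fry called 5. The probe set count was 34 without 6-month replicate 2, 19 and 15 without 18-month replicates 1 and 2, and 127 with the 4 arrays that stand apart as a block. It was 15 with a separate fit of each tissue and 3 without the 3 cord arrays richest in muscle transcripts, an omission that leaves 1 array at 6 months, assumed to vary like the other groups.

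At 30 months against 6 months in the cord, the class II gene RT1-Bb rose 3.28-fold, from 362 ± 116 to 1215 ± 557 (n = 3 each, adjusted p = 0.0127), Lgals3 rose 3.25-fold to 1540 ± 832 and Gpnmb rose 3.22-fold to 1112 ± 586 (both adjusted p = 0.0127). Mgst1, a glutathione transferase of membranes, rose 1.75-fold, from 1690 ± 76.2 to 2979 ± 416 (adjusted p = 0.0127). Aacs, acetoacetyl-CoA synthetase, fell 1.70-fold, from 512 ± 86.8 to 298 ± 14.4, and Acss2, acetyl-CoA synthetase, fell 1.52-fold from 1885 ± 197 (both adjusted p = 0.0142). Beside these changes, the skeletal muscle list was lower in the cord at 30 months (camera adjusted p = 0.000356, adjusted p = 0.2 with an estimated correlation).

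RT1-Db1 (log2 change 1.56), Fcgr2b (1.22), RT1-Da (1.15), Plek (1.12), the lysosomal and endosomal protease Ctse (0.91) and Ppih (0.83) also rose in the cord at 30 months, with adjusted p between 0.0127 and 0.0407. Cyp51 fell by 0.60, Mpnd fell by 0.57 and Gnb2 fell by 0.55, although the other probe set of Gnb2 differed by 0.16. Of 18 microglia markers 3 rose (Lgals3, Gpnmb, Fcgr2b), 12 did adjusted over the list alone and all 18 were positive, with Fcer1g at 0.52 not past the test (median 0.42, camera adjusted p = 1.63e-14, adjusted p = 0.0946 with an estimated correlation). Antigen presentation had 3 of 15 members risen and 9 adjusted over the list alone, with RT1-Ba at 1.20 not past the test (camera adjusted p = 2.8e-10, adjusted p = 0.153 with an estimated correlation). No member of the cholesterol synthesis list passed over all probe sets, and 9 fell and 1 rose adjusted over the list alone. Its members included Msmo1 at -0.70 (adjusted p = 0.0643), Lss at -0.56 (0.0515), Sc5d at -0.52 (0.103) and Sqle at -0.49 (0.1), with a median of -0.35 (camera adjusted p = 3.46e-11, and 0.0015 with an estimated correlation). Oxidative phosphorylation had 0 of 55 past the test over all probe sets or adjusted over the list alone, with Atp5f1a and Atp5f1d at -0.35, Ndufv1 at -0.31 and Uqcrq at -0.25 (median -0.11, camera adjusted p = 0.000117, adjusted p = 0.478 with an estimated correlation).

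For 30 months against 6 months in the cord, limma called 21 probe sets, 16 higher and 5 lower, for 14 and 5 named genes. Of 9 lists that camera called, 1 held with an estimated correlation, cholesterol synthesis, and fry called 4: microglia markers, antigen presentation, cholesterol synthesis and, as lower, midbrain and monoamine neurons. The last (median -0.14, fry adjusted p = 0.0182) was not called by camera (adjusted p = 0.0537). With no filter 15 probe sets were called, and the balance turned, to 5 higher and 10 lower. The probe set count was 43 without 6-month replicate 3, 13 without 30-month replicate 1 and 0 without 30-month replicate 3. It was 0 with a separate fit of each tissue, 72 with the 4 arrays that stand apart as a block, 4 without the 3 cord arrays richest in muscle transcripts and 2 with the muscle list as a covariate.

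**Figure D3:**
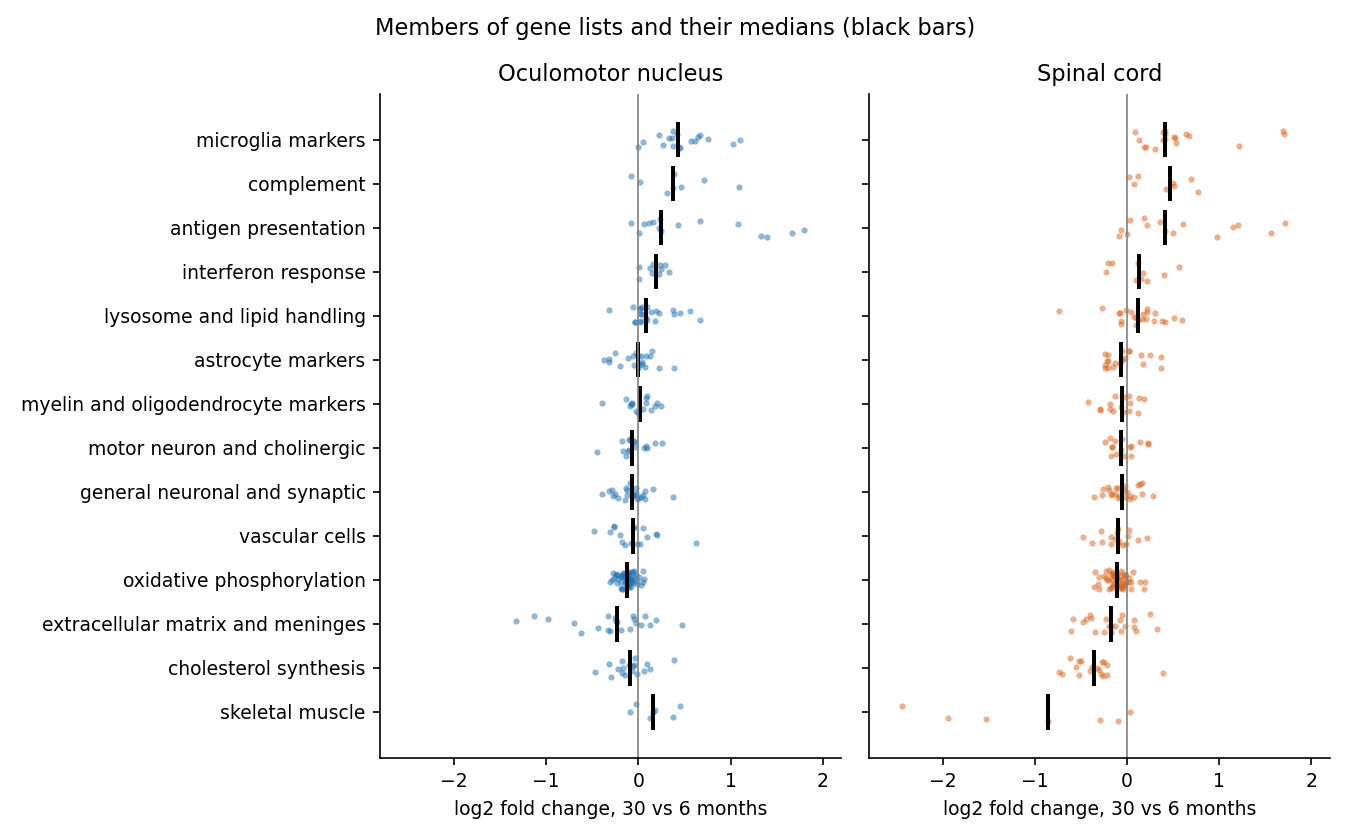
Log2 fold change of each member of 14 gene lists (points) and the median of each list (bars) at 30 months against 6 months in both tissues. Medians of microglia markers are 0.43 in the oculomotor nucleus and 0.42 in the cord, and that of cholesterol synthesis is -0.35 in the cord.

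Taking all ages at once, RT1-Da differed most clearly in the oculomotor nucleus (limma's F, adjusted p = 0.000633), followed by C3 (0.00257) and Cd74 (0.0049). In all 8 probe sets differed there, the others being Golm1, Pbx3, Slc13a4, Igf2 and Mpeg1. In the cord 39 did, with C3, Gpnmb, RT1-Db1, RT1-Bb, Fcgr2b and Lgals3 sharing the smallest adjusted p, 0.00471. Direct contrasts of 30 with 18 months, chosen after seeing the data, called 1 probe set in each tissue: RT1-Da, higher by 1.26 in the oculomotor nucleus (adjusted p = 0.0313), and Limk1, higher by 0.88 in the cord (adjusted p = 0.0305). The oculomotor count of 8 became 3, 3 and 4 without 6-month replicates 1, 2 and 3, and 18 and 5 without 30-month replicates 1 and 3. The cord count of 39 became 23 without 6-month replicate 2, and 23, 20 and 79 without 18-month replicates 1, 2 and 3. It was 0 with a separate fit of each tissue, 5 without the 3 cord arrays richest in muscle transcripts and 93 with the 4 arrays that stand apart as a block.

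Whether the tissues shared their changes at 30 months was tested on the calls of each. C3, Fcgr2b, Golm1, Mpeg1, Plek, RT1-Da and RT1-Db1 rose in both tissues, 7 probe sets where 0.0287 would be shared by chance (Fisher's exact test, 2-sided, p = 1.62e-16). This p and the chance value take the calls of the tissues as independent, which a shared estimate of the spread per probe set and a link between same-numbered arrays at 30 months, not excluded, may break. With a separate fit of each tissue or no filter the overlap was 0. It was also far lower with a replicate block within each tissue and with the muscle covariate, as given with the processing below. No probe set fell in both or moved in opposite directions, 13 were called in the oculomotor nucleus alone and 14 in the cord alone. Of the 20 oculomotor calls 19 had the same sign in the cord, and of the 21 cord calls 17 had the same sign in the oculomotor nucleus. Across the 9482 probe sets, which are not independent replicates, Pearson's r of the log2 changes was 0.27 and Spearman's rho 0.23. The overlap of 7 became 2, 2 and 3 without oculomotor 6-month replicates 1, 2 and 3, 3 without 30-month replicate 2 and 3 without 30-month replicate 3. For the cord it became 3 and 4 without 6-month replicates 2 and 3, and 4, 3 and 0 without 30-month replicates 1, 2 and 3.

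**Figure D4:**
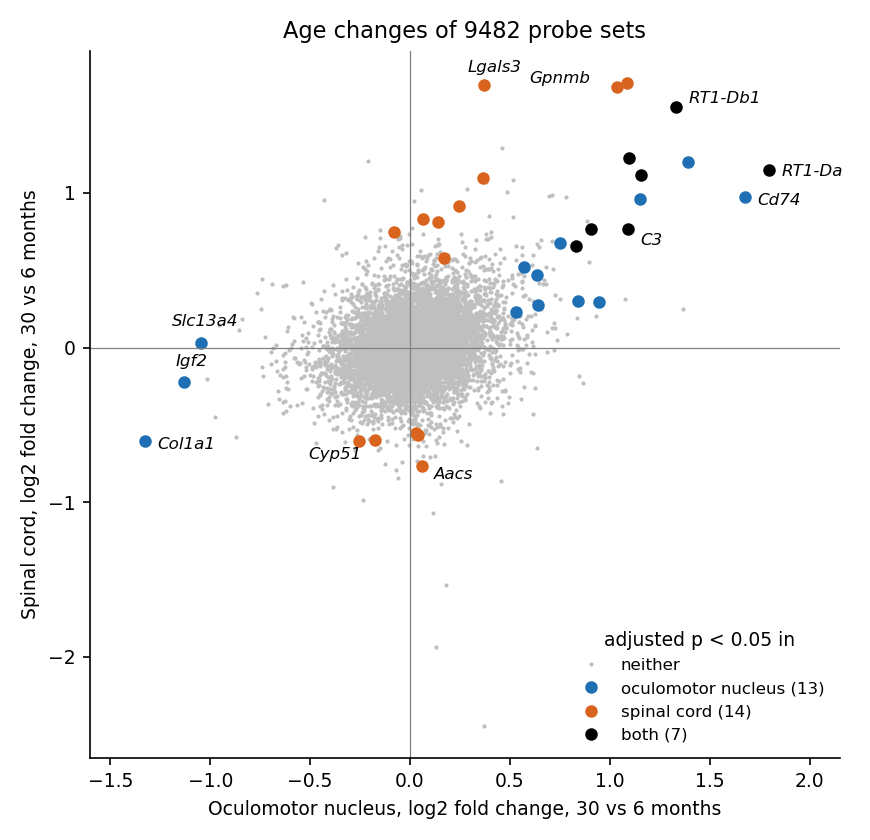
Log2 fold change at 30 months against 6 months of 9482 probe sets in the oculomotor nucleus (horizontal) and the spinal cord (vertical). Black points are the 7 probe sets called in both tissues, blue the 13 called in the oculomotor nucleus and orange the 14 called in the cord, and all 7 shared calls lie above 0 on both axes.

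The difference between the tissues in the change from 6 to 30 months was tested directly, as oculomotor change minus cord change. Cholesterol synthesis was the list with the smallest p: 16 of its 18 members had a positive difference, that is, a smaller fall or a larger rise in the oculomotor nucleus. Msmo1 differed by 0.77, Ebp by 0.70, Lss by 0.65 and Cyp51 by 0.47, none of them past the test over all probe sets, and 2 members passed adjusted over the list alone. The list's mean difference was 0.28 and its median 0.20 (camera adjusted p = 7.38e-05, and 0.0425 with an estimated correlation). Skeletal muscle was the other list called, with a mean of 1.19 and 0 of 7 members past the test, 2 adjusted over the list alone (camera adjusted p = 0.000423, adjusted p = 0.515 with an estimated correlation), beside the Acta1 signals of the cord at 6 months. Without cord 6-month replicate 2 the muscle mean was 0.77.

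No probe set passed limma's test of the difference between the tissues, and 519 had an unadjusted p under 0.05. The 10 named genes, not past the test, were Slc13a4 (difference -1.08) and Atg13 (0.76), both with an adjusted p of 0.504, Aacs (0.83), Mpnd (0.60), Klc1 (0.82), Polb (-0.97), Tprn (0.71) and Fibin (-1.03), all at 0.635, and Pacsin3 (0.85) and Lss (0.65), both at 0.665. Without cord 6-month replicate 1 the count was 1.

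At 6 months the oculomotor and cord samples were set apart by regional genes. These differences describe the dissected samples, and the share of neighbouring midbrain tissue in the oculomotor samples was not measured. Th was 22.6-fold higher in the oculomotor nucleus, at 2563 ± 290 against 114.5 ± 23.3 (n = 3 each, adjusted p = 4.38e-11), and Slc6a4 (1398 ± 136 against 99.5 ± 26.8), the serotonin transporter, 14.3-fold higher (adjusted p = 3.02e-12). Hoxd8, a homeobox gene of the trunk, was at least 16.0-fold lower in the oculomotor nucleus, at 83.7 ± 37.0 against 1406 ± 267 (adjusted p = 4.38e-11), and Hoxa5 at least 11.2-fold lower, at 60.8 ± 45.9 against 886 ± 185, with 1 and 2 of the 3 oculomotor arrays at the floor. Calca, the gene of calcitonin gene-related peptide, was at least 10.3-fold lower, at 52.3 ± 5.01 against 687 ± 76.3, with every oculomotor array at the floor.

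Higher in the oculomotor nucleus were also the vesicular monoamine transporter Slc18a2 (log2 difference 3.61), the dopamine transporter Slc6a3 (3.20), Cartpt (3.13), the vesicular glutamate transporter Slc17a7 (2.97), Nat8f5 (2.63), Tcf7l2 (2.25), Svop (2.01) and Bex1 (1.99). Lower were S100a4 (-3.12, a difference limited by 1 oculomotor array at the floor), Tnnc2 (-2.86), Mylk (-2.64), Atp2a1 (-2.46), S100a6 (-2.44), Art3 (-2.38) and Tpm1 (-2.37, with -0.92, -0.79 and -0.36 for its other probe sets). Tnnc2 and Atp2a1 are skeletal muscle genes, and Atp2a1 had 1019 ± 904 in the cord. Of 12 midbrain and monoamine genes 9 were higher (camera adjusted p = 1.93e-11, and 0.000226 with an estimated correlation), as many as adjusted over the list alone, where 1 was lower. Of 13 GABA and glycine genes 6 were higher and 1 lower, 7 and 1 adjusted over the list alone, with Gad2 at 1.91, Gabrb2 at 1.88, Glra2 at 1.86 and Gad1 at 1.22 (camera adjusted p = 0.00227, adjusted p = 0.121 with an estimated correlation).

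Motor neuron and cholinergic genes were lower in the oculomotor samples at 6 months, 10 of 16, with 2 higher, and the same counts adjusted over the list alone (camera adjusted p = 7.58e-06, and 0.0127 with an estimated correlation). Slc18a3, the vesicular acetylcholine transporter, differed by -2.09, Sncg by -1.55, the neuronal filament Prph by -1.38 and Chat by -1.27. Extracellular matrix and meninges genes were lower in 18 of 22 cases, and in 18 adjusted over the list alone, with the proteoglycan Dcn at -2.14, Col3a1 at -2.05, Ogn at -1.85 and Bgn at -1.49 (camera adjusted p = 2.94e-12, and 0.0239 with an estimated correlation). Microglia markers were lower in 15 of 18 cases, and in all 18 adjusted over the list alone, among them Lgals3 at -1.63, Lyz2 at -1.42, Fcgr2b at -1.13 and Fcer1g at -0.60 (camera adjusted p = 1.04e-07, adjusted p = 0.104 with an estimated correlation). Of 16 myelin and oligodendrocyte genes 7 were lower and 1 higher, the same counts adjusted over the list alone, with Aspa at -0.85, Ugt8 at -0.82, Mog at -0.73 and Sox10 at -0.67 (camera adjusted p = 0.00162, adjusted p = 0.227 with an estimated correlation). Gfap differed by -1.19 (adjusted p = 1.89e-06) and Mbp by -0.30 (adjusted p = 0.299).

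In this comparison limma called 2478 probe sets, 1203 higher and 1275 lower in the oculomotor nucleus. Camera called 21 lists and 9 held with an estimated correlation: midbrain and monoamine, motor neuron, vascular, general neuronal, extracellular matrix, cholesterol synthesis, interferon response, oligodendrocyte precursor and Schwann cell. With the muscle list as a covariate 1172 probe sets were called, and 1536 without the 3 cord arrays richest in muscle transcripts. Atp2a1 changed direction with the muscle covariate, to a difference of 0.33 (adjusted p = 0.524).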

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

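Of the tests below, those with the muscle list as a covariate, with the 4 arrays as a block, between list medians, of Hbb and of the 3' to 5' ratios were chosen only after the result was seen, and the signal distribution, the paired probe sets and the splits were chosen before.

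The cholesterol synthesis list was shifted lower in the cord than in the oculomotor nucleus by the test of the difference itself, with a mean of 0.28 log2 and no member past the test over all probe sets, and the skeletal muscle list had a difference of 1.19 by the same test. Against muscle carried into the younger cord samples as a candidate explanation, the cholesterol difference was 0.271 with the muscle list mean as a covariate (camera adjusted p = 0.000982). Fewer myelin-forming cells in the older cord would lower both lists, but the median of the cholesterol list lay -0.30 from that of the myelin list (permutation p = 0.00013). This p takes genes as independent and does not measure the spread between arrays. With the 4 arrays that stand apart as a block, which removes only what the 4 share, the difference was 0.284 (camera adjusted p = 4.75e-05). The cord arrays among the 4 are spread evenly over the ages, so the block cannot alter the cord mean, -0.37 with and without it. Only the oculomotor mean could move, from -0.0902 to -0.0858. The block thus cannot test the 4 arrays as a source of the cord fall. Chance could not be excluded: 10 of 100 drawn splits of the arrays shifted the list as far in either direction, the highest by 0.46.

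In each tissue 3 of 18 microglia markers rose at 30 months, and the list was called by camera at the preset correlation, with medians of 0.43 in the oculomotor nucleus (adjusted p = 0.12 with an estimated correlation) and 0.42 in the cord (adjusted p = 0.0946 with an estimated correlation). A lower share of neurons might raise the markers of every other cell type. Of 4 other lists compared (astrocyte, myelin, precursor and vascular), the precursor list was the highest in both tissues. The microglial median exceeded it by 0.379 in the oculomotor nucleus (permutation p = 0.0024) and by 0.459 in the cord (permutation p = 1e-05, the smallest these permutations can give). Schwann cell genes, not among the 4, had higher medians, 0.09 and 0.20, and were not compared. These p-values take genes as independent and do not measure the spread between arrays. More blood in the older samples could not be told apart in the oculomotor nucleus, where the upper 95% bound of the change of haemoglobin beta (Hbb) reached 0.774, above the microglial mean of 0.481, while in the cord Hbb changed by -0.02 and its bound, 0.57, lay just under the microglial mean of 0.579. Against the 4 arrays that stand apart, 90.9% of the probe sets called higher at 30 months stayed called with those arrays as a block, 14 of 17 in the oculomotor nucleus and 16 of 16 in the cord, but of the 3 microglia markers called in the oculomotor nucleus Fcgr2b and Cd53 were lost (adjusted p = 0.0518 and 0.063) at changes about as large, 1.09 and 0.73. The cord arrays among the 4 are spread evenly over the 3 ages, so the block leaves every cord fold change as it was. The 16 of 16 in the cord, and with it the pooled 90.9%, therefore cannot test the 4 arrays as a source there. The block removes only what the 4 arrays share, and microglia markers did not shift with them (camera adjusted p = 0.958). It thus cannot show what a single array carries. Without cord 30 months replicate 3, one of the 4, 0 probe sets were called in the cord at 30 months. The drawn splits cannot test the overlap of 7, since the highest of the others, 0, follows from the lack of calls in either tissue with its arrays regrouped, and the change of the hexokinase 3' to 5' ratio with age in the oculomotor nucleus was not tested as a source.

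The 4 arrays deviated from their groups together in both tissues. A different distribution of signals could not account for it, since after quantile normalization their lowest correlation was still 0.225. More degraded RNA is a candidate explanation that the pooled ratios fit. The 3' to 5' ratio of a control transcript was the highest of its group in 9 of 12 cases, against 4 by chance. The cases are 3 transcripts on the same 4 arrays and are not independent. Cord 6 months replicate 1 was highest for beta-actin only, and GAPDH was highest on 2 of the 4 arrays. An effect that acts by probe set also fits, with the reserve that the arrays were picked by their values. Of the second probe sets of a gene, 62.3% differed in the same direction (95% interval 54.5% to 69.6%), against 90.9% for the difference between the tissues. These effects were not matched for size, so a weak effect on transcripts cannot be told apart from one by probe set. Whole lists also shifted with the 4 arrays by camera at the preset correlation. Ribosomal proteins (adjusted p = 4.48e-17), oxidative phosphorylation (4.64e-05), proteasome (0.00023) and myelin genes (0.00104) were higher, and GABA and glycine genes (0.00683) lower. No other list was called. Whether these shifts have a biological source was not tested.

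For any age difference in the oculomotor nucleus, 1 of 100 drawn splits, the real one itself, gave as many as 8 probe sets, and the highest other split gave 3. Chance alone was thus an unlikely source of the count but was not excluded, since the count was itself 3 without 6-month replicate 1 or 2. In the cord chance was not excluded either: the real count was 39, the highest other split gave 192, and 9 of 100 drawn splits gave as many, which points to a structure of the samples. For the difference between the tissues the splits cannot test the count of probe sets, since all 100 reach the real count of 0, and the highest, 71, again points to structure. For its lists chance was not excluded, with 2 lists against 15 (88 of the 100 splits gave 2 lists or more).

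The 6 arrays of each comparison of 2 groups allow only 10 splits, too few for a share under 0.05. For probe sets, the real count and the highest other split were 0 and 1 at 18 months in the oculomotor nucleus, where a count of 0 tests nothing, 20 and 0 at 30 months there, 69 and 3 at 18 months in the cord, 21 and 0 at 30 months there, and 2478 and 1 between the tissues. For lists they were 10 and 6, 7 and 15, 11 and 12, 9 and 10, and 21 and 17 in the same order. As many lists as the real grouping, itself included, came from 1, 4, 3, 3 and 1 of the splits, and 15 lists where the real grouping gave 7 points to a structure of the samples.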

How the results depend on the processing

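Alternatives with the 4 arrays as a block or left out, with the muscle covariate and without the 3 muscle-rich cord arrays were chosen after seeing the data, and the others before. The block lowers the spread within groups by construction and leaves the cord fold changes as they were. Counts of probe sets are given where they moved, and unless stated the cause was not tested. Values as deposited left nothing to compare, because the arrays were already scaled alike, and a separate fit of each tissue cannot compare the tissues.

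At 30 months in the oculomotor nucleus the 20 calls became 8 with a pseudocount in place of the floor, 8 with no filter (15866 probe sets tested), 12 with the stricter filter (6287 tested), 12 with the muscle covariate and 12 without the 3 muscle-rich cord arrays. At 18 months in the oculomotor nucleus the 0 calls became 2 with array weights, 2 with the 4 arrays left out, and 7 when all pairs of arrays had to differ in the same direction, with a change over 1.70-fold and no p. At 18 months in the cord the 69 calls became 15 with a separate fit of each tissue, 33 with a change over 1.70-fold required, 127 with the 4 arrays as a block, 126 with them left out and 3 without the 3 muscle-rich cord arrays. At 30 months in the cord the 21 calls became 0 with a separate fit, 7 with array weights, 33 by the same criterion of all pairs, 72 with the 4 arrays as a block, 2 with the muscle covariate and 4 without the 3 muscle-rich arrays.

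With no filter the calls at 30 months in the cord were 15, 5 higher and 10 lower, against 16 and 5. Median centring left 71.4% of the calls at 30 months in the oculomotor nucleus higher, against 85.0%. For any age difference, the 8 oculomotor probe sets became 5 with no filter, 5 without trend and 31 with array weights. The 39 cord probe sets became 0 with a separate fit, 62 with array weights, 93 with the 4 arrays as a block, 108 with them left out and 5 without the 3 muscle-rich arrays. The overlap of 7 became 4 with quantile normalization, 4 with a pseudocount, 0 with no filter, 4 with the stricter filter, 0 with a separate fit, 3 with array weights, 11 with the 4 arrays as a block, 1 with the muscle covariate and 0 without the 3 muscle-rich arrays. The difference between the tissues in the age change gave 2 probe sets with no filter. Between the tissues at 6 months, 1172 were called with the muscle covariate and 1536 without the 3 muscle-rich arrays, where the cord at 6 months keeps 1 array. The muscle gene Atp2a1 alone changed direction, to a difference of 0.33 between the tissues (adjusted p = 0.524) with the muscle covariate, which by construction removes what follows the muscle list.

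Replicate numbers were not taken as pairs. Within a tissue, 5 of 18 arrays correlated best with one of their own number at another age. Between the tissues, arrays of 1 number correlated at 0.121 to 0.501 at 30 months, where every pair exceeded 0.1, but at 0.0343 to 0.095 at 6 months and -0.059 to 0.0303 at 18 months. At 30 months replicate 3 of both tissues is among the 4 arrays that stand apart, whose highest correlation with each other was also 0.501. A link by number at 30 months thus cannot be told apart from that shared deviation. It is not excluded, and it bears on the overlap. A replicate block of age and number gave 2636 probe sets between the tissues and 0 for the difference in the age change. With a replicate block within each tissue the counts were 9 at 30 months in the oculomotor nucleus, 40 and 2 at 18 and 30 months in the cord, 5 and 22 for any age difference in the oculomotor nucleus and the cord, and 1 for the overlap.

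Leaving out 1 array at a time gave 0 to 0 calls at 18 months in the oculomotor nucleus, 4 to 69 at 30 months there, 15 to 100 at 18 months in the cord, 0 to 43 at 30 months there, 3 to 18 and 20 to 79 for any age difference in the oculomotor nucleus and the cord, 0 to 6 for the overlap, 0 to 1 for the difference between the tissues in the age change, and 1834 to 2346 between the tissues. Camera with an estimated correlation called 0 and 0 lists in the oculomotor nucleus at 18 and 30 months, 4 and 1 in the cord, 1 for the difference between the tissues in the age change and 9 between the tissues, and fry called 0, 3, 5, 4 and 1 in the first 5 of these. With the muscle covariate 1 list was called for the difference in the age change. Values for single genes and lists were compared once per alternative. Of these comparisons 3257 were classed as the same, which does not mean identical, 454 as weaker, 33 as stronger and 1 as reversed. The first class includes 151 gene values as deposited, which left nothing to compare, and 831 gene values with an array left out. With an estimated correlation 45 list values were weaker and 15 the same.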

Other observations

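The tissue lists that hold with an estimated correlation at 6 months extend beyond neurons. In the oculomotor nucleus, 11 of 24 general neuronal and synaptic genes were higher and 1 lower (camera adjusted p = 0.000199), with the growth cone protein Gap43 at 1.34 and the synaptic vesicle proteins Sv2a at 1.25, Vamp2 at 1.16 and Syn2 at 0.94. Lower were 10 of 17 vascular genes (3.17e-05), with Tagln of smooth muscle at -1.70, 5 of 10 oligodendrocyte precursor genes (0.00686), with Enpp6 at -1.54, and 3 of 6 Schwann cell genes (0.00126), with the peripheral myelin gene Pmp22 at -1.67. Also lower were 10 of 18 cholesterol synthesis genes (0.000263), with Lss at -1.16, and 4 of 10 interferon response genes (0.00253), with Ifitm3 at -1.07.

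Other tissue lists were called by camera and lost with an estimated correlation (adjusted p in brackets, preset then estimated). Higher in the oculomotor nucleus were glutamate receptors (0.00496, 0.104), with Gria2 at 1.16, and glycolysis (0.00227, 0.119), with Ldha at 1.01. Lower were complement (3.41e-05, 0.105), with Serping1 at -2.14, antigen presentation (0.000221, 0.174), with Cd74 at -2.11, astrocyte markers (0.00227, 0.119), with Fabp7 at -1.04 but Slc1a3 at 1.09, neurotrophic factors and receptors (0.0213, 0.119), with Cntf at -1.22, and antioxidant genes (0.00596, 0.166), with ceruloplasmin (Cp) at -1.50. Lysosome and lipid handling (0.0155, 0.292), with Scd at -1.71, and skeletal muscle (0.00227, 0.146), with Acta1 at -2.19, were lower too.

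Lists called in age comparisons and not described so far are given in the same way. In the oculomotor nucleus at 18 months, complement (0.00145, 0.347), interferon response (0.000782, 0.104), with Irf7 at 0.38, and Schwann cell genes (0.0361, 0.244) were higher. Motor neuron genes (0.0128, 0.244), with Slc5a7 at -0.34, oxidative phosphorylation (1.08e-05, 0.514), cholesterol synthesis (0.0128, 0.244), with Tm7sf2 at -0.49, extracellular matrix (4.05e-05, 0.244), with Col1a1 at -0.89, and glucocorticoid responsive genes (0.0387, 0.514) were lower. The glucocorticoid mean of -0.13 was -0.25, -0.07 and -0.08 without 6-month replicates 1, 2 and 3, and leaving out 1 array could also end the calls of the motor neuron, cholesterol synthesis and Schwann cell lists. At 30 months there, interferon response (0.00854, 0.12) had all 10 members positive, with Bst2 at 0.33, and lysosome and lipid handling (0.00854, 0.416) had Npc2 at 0.56, and leaving out 1 array could end either call.

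In the cord at 18 months the interferon response list was higher (camera adjusted p = 0.000324, and 0.0259 with an estimated correlation), with Rsad2 at 0.73, Ifitm3 at 0.68 and Irf7 at 0.63, none past the test over all probe sets and 3 members past it adjusted over the list alone. Ribosomal proteins were called higher (0.0339, 0.65), but their mean of 0.11 was 0.02 without 18-month replicate 3, one of the 4 arrays that stand apart, and 0.055 without 6-month replicate 2, with the call lost. Myelin genes (0.0485, 0.539), with Mog at -0.40, GABA and glycine genes (0.029, 0.367), with Gad2 at -0.53, oxidative phosphorylation (0.000877, 0.539) and skeletal muscle (0.0121, 0.367) were called lower. The myelin mean of -0.10 was -0.03 without 18-month replicate 2 and -0.19 without replicate 3, and the GABA and glycine mean of -0.22 was -0.13 without replicate 3. The calls of both lists were lost without replicate 2 and replicate 3, respectively (camera adjusted p = 0.446 and 0.251), and that of oxidative phosphorylation without 6-month replicate 1 (0.103). The myelin call was also lost without 6-month replicates 1 and 3 (0.219 and 0.129) and 18-month replicate 1 (0.146). The GABA and glycine call was also lost without 6-month replicates 1 and 3 (0.106 and 0.131). The muscle mean of -0.60 was -0.18 and -1.14 without 6-month replicates 2 and 3, and -0.31 and -0.92 without 18-month replicates 1 and 2, with the call lost at the 2 smaller values. It was also lost without 6-month replicate 1, at a mean of -0.48 (camera adjusted p = 0.106). At 30 months complement (8.5e-05, 0.2) was higher, with a mean of 0.39, and 0.25 without 30-month replicate 3. Lysosome and lipid handling (0.0414, 0.478) was called higher, but its mean of 0.11 was 0.02 without replicate 3, with the call lost. Extracellular matrix (0.00517, 0.478), with Col6a1 at -0.59, vascular genes (0.0374, 0.2) and skeletal muscle (0.000356, 0.2), with Atp2a1 at -2.45, were called lower. The extracellular matrix mean of -0.17 was -0.09 without 6-month replicate 3, the vascular mean of -0.11 was -0.06 without 30-month replicate 3, with both calls lost (adjusted p = 0.211 and 0.189), and the muscle mean of -1.02 was -0.60 and -1.56 without 6-month replicates 2 and 3. Atp2a1 had 1019 ± 904 in the cord at 6 months and 127 ± 21.7 at 30 months.

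Camera called none of the lists of neurons, astrocytes or myelin at 30 months in either tissue, while fry called midbrain and monoamine neurons lower in the cord. Motor neuron genes had medians of -0.07 in the oculomotor nucleus and -0.06 in the cord (camera adjusted p = 0.468 and 0.43), astrocyte markers -0.01 and -0.06 (0.785 and 0.355), and myelin genes 0.02 and -0.05 (0.769 and 0.178). General neuronal genes had -0.06 in both (0.154 and 0.227). Lists that camera called in no comparison of the main fit, that is, with no alternative setting, with their lowest adjusted p, were blood and choroid plexus (0.278), calcium buffering and pumps (0.168), cell cycle arrest and DNA damage (0.0639), chaperones (0.355), circadian clock (0.549), immediate early genes (0.0955) and proteasome (0.0575). Hox genes, with 2 kept, were not tested as a list.

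With the 4 arrays that stand apart as a block, a setting chosen only after the result was seen, 127 probe sets passed the test in the cord at 18 months and 72 at 30 months. The 4 arrays were picked by their deviation from their groups, so the block lowers the spread within groups by construction. It left the cord fold changes as they were, and the further cord calls rest on that lower spread. Their adjusted p may thus be too small. The further genes were of several kinds, also outside immunity and sterols, such as Pfkm and Cend1 at 18 months and Zmynd11 and Fbxo11 at 30 months. Those given next were picked as microglial, class II or sterol genes. At 18 months these included Csf1r (0.51, adjusted p = 0.0368), the receptor that microglia need to survive, Tyrobp (0.74, 0.0361) and the cholesterol synthesis genes Tm7sf2 (-0.74, 0.0428) and Dhcr7 (-0.51, 0.0356). At 30 months they included Cd74 (0.97, 0.0373), the sterol transporter Abcg1 (-0.88, 0.0369), Msmo1 (-0.70, 0.0297) and Lss (-0.56, 0.0297). Lists that camera called with this block and in no comparison of the main fit were proteasome and ubiquitin, lower in the oculomotor nucleus at 18 and 30 months (0.0402 and 0.000575) and higher there than in the cord at 6 months (0.0246), and cell cycle arrest and DNA damage, lower there than in the cord at 6 months (0.0415). Without the block, camera with an estimated correlation gave the proteasome list adjusted p of 0.717 and 0.777 at 18 and 30 months. At 30 months its mean log2 signal in the oculomotor nucleus was low on replicate 2 alone, 10.55 against 10.76 and 10.82, with 10.74 to 10.78 at 6 months. At 6 months oxidative phosphorylation was also called higher (0.00902) and the glucocorticoid responsive list lower (0.0246) in the oculomotor nucleus. Without the block, camera called neither of them at 6 months, at the preset or an estimated correlation. The calls at 18 and 30 months in the cord without the block, 69 and 21, were all kept with it, which the unchanged fold changes and the lower spread favour.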
